A study of Mus musculus with 3 samples.

How the data were processed

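Kidney RNA of mice was measured on 3 two-colour arrays, each carrying 1 mouse injected with an antibody against the glomerular basement membrane (GBM) 1 day earlier. Per the labels, the RNA of each anti-GBM mouse carried Cy5 and the RNA of a pool of 5 normal BALB/c mice carried Cy3, on every array. The arrays are named here by the mouse, 11, 12 and 13, which are replicates 1, 2 and 3. The mice are separate animals, per the labels. The pool is a single control sample, so the test of the log ratio against 0 leaves out the spread between control mice. With no array of swapped dyes, a dye bias of a probe stays in its log ratio.

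The deposited table gives 1 value per row and array, and the authors' steps that made it (scanner, background correction, normalization, flags) are not given in the sources used here. The deposited values are read as log ratios of the 2 channels, not intensities. They run from -3.62 to 2.74 and have a median of 0 on each array. Without the exact zeros the medians are 0.0077, 0.0105 and 0.01. Their base is not stated and could not be settled from the values, so the planned conversion to log2 was not made. They are left on the deposited scale, and a fold is given for base 2 and for base 10. The test statistics do not depend on the base. The direction is not stated either. It was read as anti-GBM over control, which is likely because Cy5 over Cy3 is the usual order for such tables and the labels put the anti-GBM RNA in the Cy5 channel. If the ratio ran the other way, every sign below would turn. Signal brightness and spot flags were not used here, so the planned filter on dim rows was not run. The number of arrays limits the precision.

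The table has 16281 rows. Between 29.5% and 33.7% of the values of an array are exactly 0. These were read as no estimate, not as an equal level, and 9682 rows (59.5%) with a value other than 0 on all 3 arrays were tested. Row names came from the platform annotation supplied with the table, in which 13738 rows name 1 gene, 52 name several and 2491 are not listed. The gene numbers of 13694 of the named rows were found in a RefSeq table (GRCm38.p6), and no symbol needed an update. Rows naming several genes or none stayed out of the gene fit. Rows of 1 gene were averaged per array, which left 7235 genes.

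Each array was centred on its median over the values other than 0. An intercept-only linear model was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default settings), and Benjamini-Hochberg adjusted p under 0.05 was the threshold. Adjusted p-values of single genes below are from this fit. The prior had 5.55 degrees of freedom for the gene fit, to which each gene adds the spread of its 3 arrays. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the table and drew the figures.

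There were 34 gene lists, fixed with the test, the named-gene rule and most alternatives before the data were examined. They hold 771 different genes, of which 648 have a row. Each list was compared with all other genes by camera with a preset correlation of 0.01, adjusted over the 34 lists, and again with an estimated correlation. The estimated correlation rests on 3 arrays, and camera then has only the few degrees of freedom that these arrays leave. A list could hardly pass that setting after adjustment, so it cannot decide whether a list shifted. No list passed it, and the lowest adjusted p was 0.427. The fry test asks whether a list's genes move, on balance, in 1 direction, without comparing them with other genes. Genes were named by rule: the 12 highest and 12 lowest among those past the threshold with the same sign on all 3 arrays, up to 4 members per list with the smallest p, and 14 genes chosen in advance. Lcn2, Havcr1, Icam1, Nfkb1, C3, Umod and Actb, among these 14, had no row measured on all 3 arrays, and 1 of the 14 is not reported here. Other called list members are named too where their count is small or their call ended with 1 mouse left out, chosen after their values were seen. Where rows of a gene disagree in sign, this is said. A call that ended when 1 mouse was left out is named with its highest adjusted p among the 3 refits. These refits have fewer arrays and called 726 to 1032 genes against 1407. A lost call can therefore come from lost power and does not show that the gene's shift rested on that mouse. No coordinates are given, because the build behind the probes is not given in the sources used here.

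The fit was tested on simulated data for 7235 genes with the spread of this comparison. It called 60 of 100 genes shifted by 0.5, 1 of 100 genes shifted by 0.25 and 4 of 7035 genes with no shift. The list test called a list shifted by 0.3 and 0 of the 33 other lists. The simulated errors were independent between genes and arrays, while the real arrays share a pool and a dye orientation. Far fewer genes were shifted than the 1407 past the test in the real data, so the adjustment was stricter in the simulation. The simulation therefore gives no rate of false or missed calls for the real data.

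Alternatives were no centring, scaling to a common spread, quantile normalization, each replicate left out, rows measured on at least 2 arrays, robust moderation, a plain test without moderation, 1 row per gene, a limit of 2-fold, other camera settings and the sign turned. After seeing the data 3 more were added: exact zeros kept as values, each array's local median subtracted, and rows in stretches crowded with very low values left out. For the local median, row numbers were laid out as 119 lines of 156 places. This layout was inferred, because deviations of an array from the row mean correlated over a distance of 156 row numbers (0.17 to 0.275) about as much as over a distance of 1 (0.2 to 0.288). The window was 15 places by 7 lines. A crowded stretch was any row with 3 or more other rows of mean log ratio below -1 within 100 row numbers, where means were taken before centring over the 11074 rows measured on 2 or 3 arrays.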

Results

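Kidney RNA was compared between mice with early anti-GBM glomerulonephritis and normal mice. In this model an injected antibody binds the glomerular basement membrane, the filter layer between the capillaries and the podocytes, and inflames the glomeruli. There was 1 group of 3 BALB/c mice, studied 1 day after injection, and each mouse had its own 2-colour array with the pooled RNA of 5 normal mice in the other channel. Values other than 0 were listed for 10898, 10789 and 11483 rows of mice 11, 12 and 13. All values below are means of deposited log ratios ± SD over n = 3 mice, on a log scale of unstated base. Positive values are likely higher in the anti-GBM kidneys, because the labels place their RNA in the red channel and red over green is the usual ratio, but the direction is not stated.

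The first question was which transcripts differed between kidneys 1 day after the antibody and normal kidneys. Of 7235 genes, 686 were higher and 721 were lower past the test, together 19.4%. The serum amyloid gene Saa2, an acute-phase gene, had the highest mean log ratio, 2.00 ± 0.42, which is 4.01-fold if the base is 2 and 101-fold if it is 10. Tagln, a smooth muscle actin-binding protein, reached 1.93 ± 0.23, and the calcium-binding proteins S100a6 and S100a9 reached 1.88 ± 0.14 and 1.42 ± 0.38. Several of the 12 highest genes act in cell division. Among them were the mitotic kinase Pbk (1.61 ± 0.10), the kinetochore genes Cenpk (1.41 ± 0.25), Cenph (1.36 ± 0.12) and Ska1 (1.32 ± 0.08), the chromatin remodeller Hells (1.30 ± 0.42) and the proliferation marker Mki67 (1.24 ± 0.14). The row of Hells and a row of Pbk lie in stretches of row numbers crowded with very low values. Cyp24a1, the vitamin D 24-hydroxylase, was at 1.39 ± 0.29 and 2700099C18Rik at 1.37 ± 0.23. Adjusted p of these 12 lay between 7.07e-05 and 0.00236. At row level, 925 of 9682 rows were higher and 977 were lower. The counts rest on ratios against a single pool and 1 dye orientation, and without mouse 11 they were 726 genes and 944 rows. A plain test without moderation called 3 genes.

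**Figure D1:**
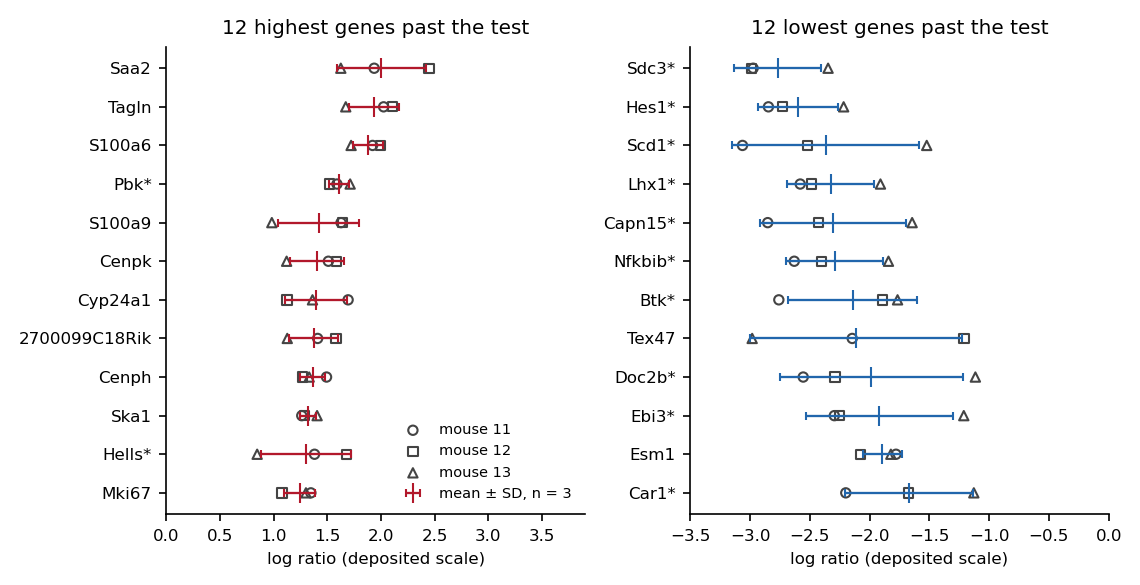
The 12 highest (left) and 12 lowest (right) genes past the test, with the log ratio on the deposited scale on each horizontal axis, a symbol for each of the 3 mice, and a vertical bar with whiskers for the mean ± SD. An asterisk marks a gene with a row in a stretch of row numbers crowded with very low values, as for 10 of the 12 lowest genes.

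The lowest genes were Sdc3, a cell-surface proteoglycan (-2.77 ± 0.37), the Notch target Hes1 (-2.60 ± 0.33), the fatty acid desaturase Scd1 (-2.37 ± 0.78) and the kidney development factor Lhx1 (-2.33 ± 0.36). They were followed by Capn15 (-2.31 ± 0.61), the NF-kB inhibitor Nfkbib (-2.29 ± 0.41), the B cell kinase Btk (-2.14 ± 0.54), Tex47 (-2.11 ± 0.89), Doc2b (-1.99 ± 0.77), Ebi3 (-1.92 ± 0.61), the endothelial proteoglycan Esm1 (-1.89 ± 0.16) and the carbonic anhydrase Car1 (-1.67 ± 0.54). Of these 12 genes, 10 had a row in a stretch crowded with very low values, the exceptions being Tex47 and Esm1. Among 11074 rows measured on 2 or 3 arrays, 68 had a mean of the deposited values below -1, and 48 of these had at least 3 others within 100 row numbers. No row above 1 had as many such neighbours among the 46 rows above 1 in the same set. Of the genes with crowded low rows, 16 had other rows outside the stretches. These 17 rows had a median of 0.08, against -1.92 for the crowded rows, which argues against lower transcript levels of those 16 genes. None of the 12 lowest genes is among them. What made rows at neighbouring numbers low was not settled here. Other low genes outside the stretches, chosen after their values were seen, were Cntnap1 (-1.58 ± 0.56), the myosin gene Myh1 (-1.27 ± 0.32) and the erythroid factor Klf1 (-0.98 ± 0.39). The anti-ageing gene Kl had a mean of -0.90 ± 0.31, but its 3 rows ranged from -2.34 to -0.18.

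**Figure D2:**
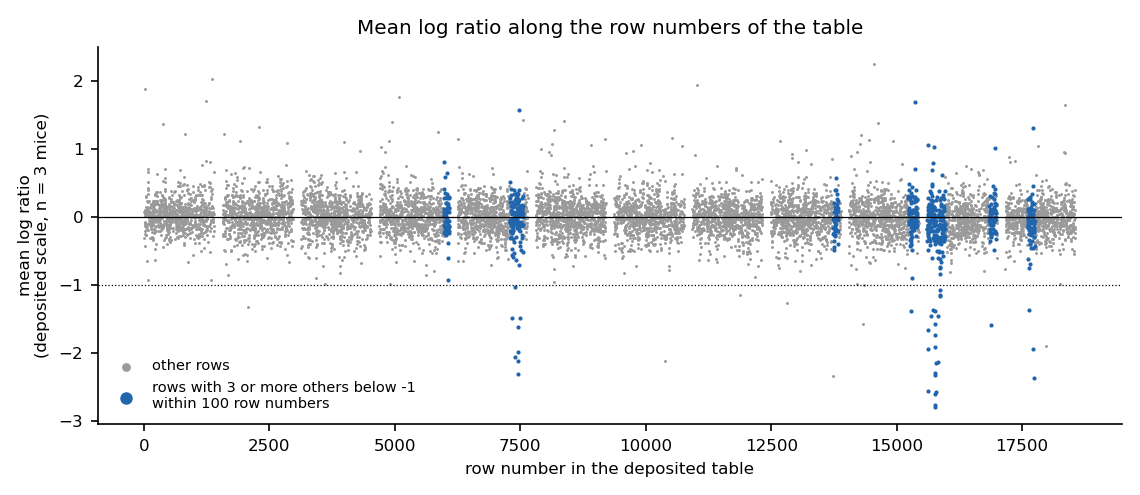
Mean log ratio of each row on the deposited scale (vertical axis, n = 3 mice) against its row number in the table (horizontal axis), with rows in crowded stretches in blue and the others in grey. Most of the values below -1, marked by the dotted line, sit in a few narrow stretches, while values above 1 are spread along the table.

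Cell cycle genes were mostly higher. Of 23 measured members 17 were higher, 0 were lower and 6 did not pass, and 21 were higher when adjusted over the list alone. The median log ratio was 0.65. Mki67 was at 1.24 ± 0.14, the DNA replication helicase subunits Mcm6 and Mcm3 were at 1.20 ± 0.19 and 0.81 ± 0.06, and the cyclin Ccna2 was at 0.92 ± 0.07. Mcm3 has its row in a crowded stretch of low values. The list differed from all other genes by camera with the preset correlation (adjusted p = 4.82e-14), but not with an estimated correlation (adjusted p = 0.427). By fry the adjusted p was 0.0125, and cell cycle is the only list of the 4 past camera that also passed fry. Among the called members, Rrm2 (0.35 ± 0.20) lost its call without mouse 12 or 13 (highest adjusted p 0.111).

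**Figure D3:**
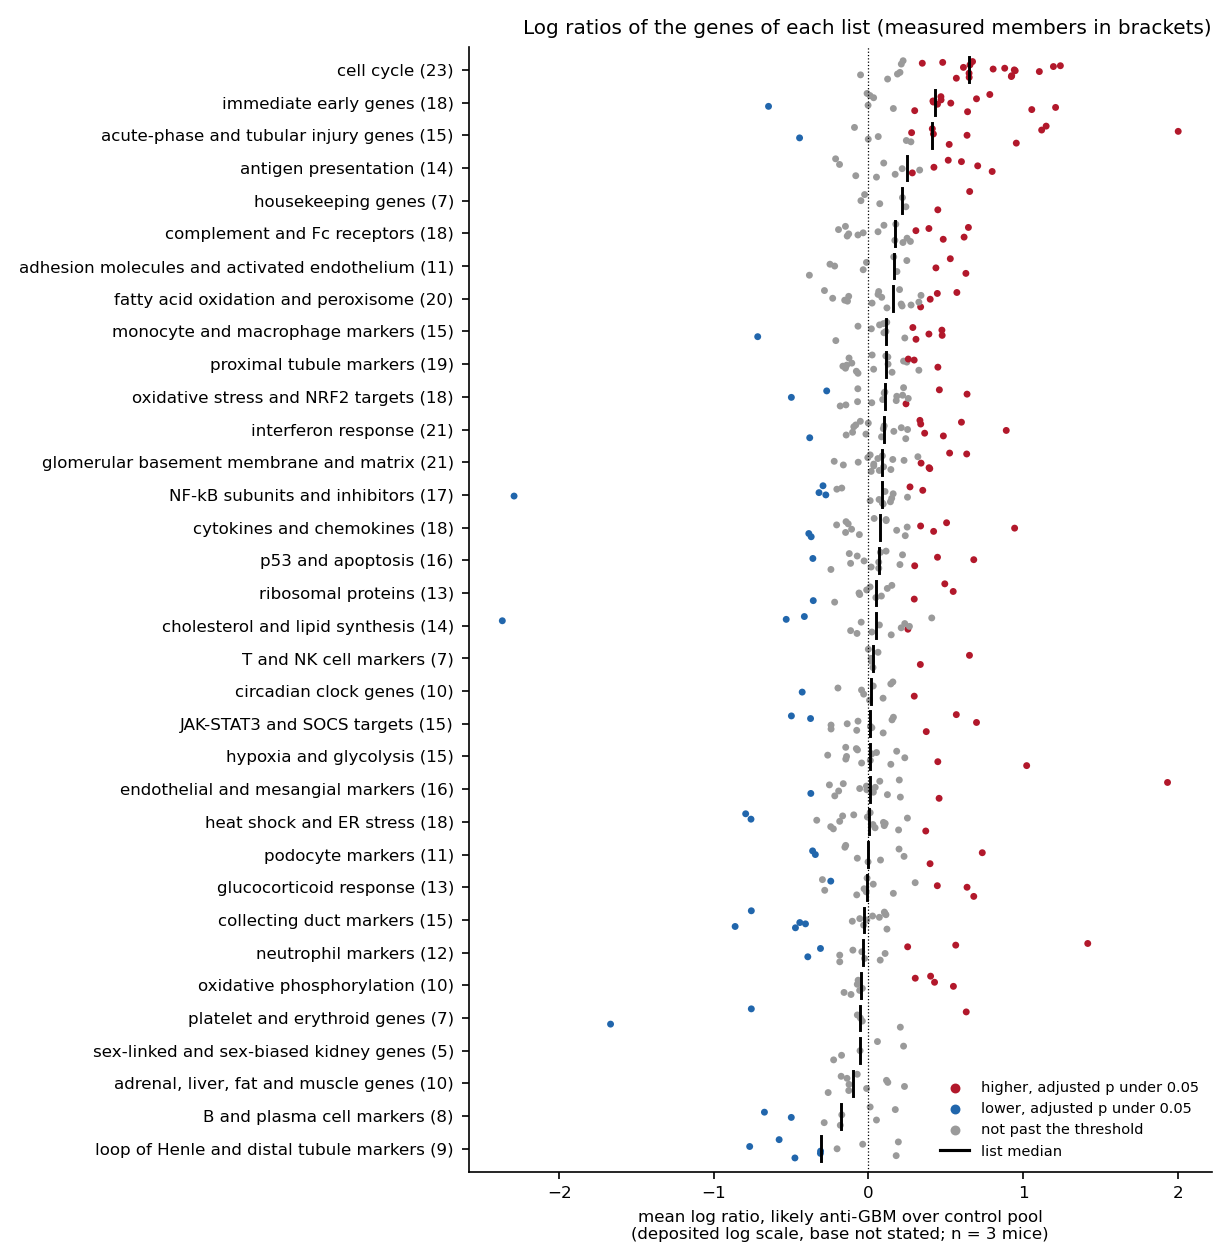
Mean log ratio of every measured gene of the 34 lists (horizontal axis, deposited log scale, n = 3 mice), 1 line of points per list, with red and blue points past the threshold and a black bar at the list median. The medians of cell cycle (0.651), immediate early (0.433), acute-phase and injury (0.413) and antigen presentation genes (0.251) are the 4 highest, and these are the 4 lists past the camera test.

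Immediate early genes, which respond within minutes to stress and growth signals, were mostly higher. Of 18 members 12 were higher, 1 was lower and 5 did not pass, with the same counts adjusted over the list alone, and the median was 0.43. Egr1 was at 1.21 ± 0.22, Ccn1 at 1.06 ± 0.15, Nr4a1 at 0.78 ± 0.06 and Junb at 0.70 ± 0.10. Ccn1 and Nr4a1 have their rows in crowded stretches. The lower member was Fos (-0.65 ± 0.38), whose rows were at -1.07 and -0.22, with the first in a crowded stretch. Camera gave an adjusted p = 4.12e-06 with the preset correlation and adjusted p = 0.81 with an estimated correlation, and fry adjusted p = 0.1.

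Acute-phase and tubular injury genes had a median of 0.41, with 9 of 15 members higher, 1 lower and 5 not passing. Adjusted over the list alone, 10 were higher and 1 was lower. The intermediate filament Vim was at 1.15 ± 0.13, the serum amyloid Saa3 at 1.12 ± 0.23 and the annexin Anxa3 at 0.96 ± 0.13, beside Saa2. The lower member was Lbp, the lipopolysaccharide-binding protein (-0.45 ± 0.11). Timp1 had a mean of -0.09 ± 0.80, and its rows disagreed, at -0.76 and 0.58. The injury marker Lcn2 was listed at 0 for mice 11 and 12 and at 0.49 for mouse 13. The list passed camera with the preset correlation (adjusted p = 3.3e-05), but adjusted p = 0.81 with an estimated correlation and 0.1 by fry. Plaur (0.42 ± 0.23) lost its call without mouse 13 (adjusted p = 0.0689), and Saa1 (0.28 ± 0.13) without mouse 11 or 12 (highest adjusted p 0.207).

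Genes of antigen presentation were higher for 6 of 14 members, with 0 lower and 8 not passing, and for 7 when adjusted over the list alone. The class I genes H2-D1 and H2-Q7 were at 0.80 ± 0.09 and 0.71 ± 0.07, the immunoproteasome subunit Psmb8 at 0.60 ± 0.21 and the peptide transporter Tap2 at 0.52 ± 0.11. The other called members lost their calls, H2-K1 (0.42 ± 0.31) without mouse 11 or 12 (highest adjusted p 0.174) and H2-Ab1 (0.28 ± 0.13) when any 1 mouse was left out (0.161). The list medians of mice 11, 12 and 13 were 0.317, 0.359 and 0.0512, so the median shift was small in mouse 13. H2-D1 (0.81), H2-Q7 (0.63), Psmb8 (0.46) and Tap2 (0.40) were still above 0 in that mouse. Class I genes are near-identical in parts, so a probe of one can bind transcripts of another. The list passed camera with the preset correlation of 0.01 (median 0.25, adjusted p = 0.00741). With the estimated correlation, which was 0.651, the adjusted p was 0.81, and by fry it was 0.142. The interferon response list did not pass (median 0.10, adjusted p = 0.0729), with 6 of 21 members higher, 1 lower and 14 not passing, and the same counts adjusted over the list alone. It passed without mouse 12 (adjusted p = 0.0462) and without mouse 13 (adjusted p = 0.0482), and over the alternatives with the preset correlation its adjusted p ranged from 0.0338 to 0.188. Its examples were the interferon regulator Irf7 (0.89 ± 0.27), Psmb8, Ifit1 (0.48 ± 0.14) and Oas1a (0.34 ± 0.05), whose row lies in a crowded stretch and whose call ended without mouse 11 (adjusted p = 0.0993). The lower member was Gbp3 (-0.38 ± 0.15), which lost its call without mouse 12 (adjusted p = 0.0648). Usp18 (0.33 ± 0.06) lost its call without mouse 11 or 13 (highest adjusted p 0.0856), and Igtp (0.36 ± 0.20) without mouse 12 or 13 (0.102).

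NF-kB subunits and inhibitors were higher for 2 of 17 members, lower for 4 and not past the test for 11, with the same counts adjusted over the list alone. The list did not pass (adjusted p = 0.971), and its median of 0.09 and its mean of -0.11 differed in sign while the test pointed up. Nfkbib, in a crowded stretch, was at -2.29 ± 0.41. The subunit Rel (-0.32 ± 0.04) and the adaptor Traf2 (-0.29 ± 0.10) lost their calls without mouse 11 or 13 (highest adjusted p 0.0947 and 0.182), and the subunit Relb (0.35 ± 0.13), also in a stretch, without mouse 11 or 12 (0.0764). The rows of Traf2 disagreed, at -0.61 and 0.02. The remaining called members, Traf1 (0.27 ± 0.09) and Nfkbie (-0.28 ± 0.13), lost their calls when any 1 mouse was left out (highest adjusted p 0.145 and 0.141). The inhibitor Nfkbia was at 0.25 ± 0.19 (adjusted p = 0.0875), at 0.14 without mouse 12 (adjusted p = 0.328) and at 0.42 with the local median subtracted (adjusted p = 0.0147).

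Cytokines and chemokines did not differ from other genes as a list (median 0.08, adjusted p = 0.478), with 4 of 18 members higher, 2 lower and 12 not passing. Adjusted over the list alone, 6 were higher and 2 lower. The inflammatory cytokine Il1b was at 0.51 ± 0.05, the B cell chemokine Cxcl13 at 0.95 ± 0.40, Cx3cl1 at 0.42 ± 0.12 and the neutrophil chemokine Cxcl2 at 0.34 ± 0.04, which lost its call without mouse 11 (adjusted p = 0.111). Cxcl13 was at 0.38 (adjusted p = 0.365) once rows measured on 2 arrays were averaged in. The monocyte chemokine Ccl2 was lower (-0.37 ± 0.09, adjusted p = 0.0164). Without mouse 11 it lost its call (adjusted p = 0.0833) but stayed at -0.34. Ccl9, in a crowded stretch, was at -0.39 ± 0.17 and lost its call without mouse 13 (adjusted p = 0.0604).

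Adhesion molecules and activated endothelium had 3 of 11 members higher, 0 lower and 8 not passing, and 4 higher and 1 lower adjusted over the list alone (median 0.16, adjusted p = 0.199). Tissue factor F3 was at 0.63 ± 0.06 with a row in a crowded stretch, thrombomodulin Thbd at 0.53 ± 0.05 and the leukocyte integrin Itgb2 at 0.44 ± 0.11. Angpt2 was at -0.38 ± 0.32 (adjusted p = 0.0583) and, with 1 mouse left out, ranged from -0.55 without mouse 11 (adjusted p = 0.00555) to -0.23 without mouse 12 (adjusted p = 0.191). The adhesion molecule Vcam1 was at 0.16 ± 0.04 (adjusted p = 0.14). Complement and Fc receptor genes were higher for 5 of 18 members, lower for 0 and not past the test for 13, and higher for 6 when adjusted over the list alone (median 0.17, adjusted p = 0.0935). Over the alternatives with the preset correlation the adjusted p of this list ranged from 0.0338 to 0.357. It passed without mouse 12 (0.0462) and with 1 row per gene (0.0338), while without mouse 11 the median was 0.08 (adjusted p = 0.125) and with the local median subtracted 0.12 (adjusted p = 0.211). C1ra was at 0.48 ± 0.09, the Fc receptor Fcgr1 at 0.65 ± 0.28 and C4b, in a crowded stretch, at 0.62 ± 0.34. The calls of Cfb (0.31 ± 0.17) and Fcer1g (0.39 ± 0.29) ended without mouse 11 (highest adjusted p 0.144 and 0.177), and also without mouse 13 for Cfb and mouse 12 for Fcer1g.

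Markers of white blood cells did not move together. Neutrophil markers were higher for 3 of 12 members, lower for 2 and not past the test for 7, with the same counts adjusted over the list alone (adjusted p = 0.895). Their median was -0.03 and their mean 0.10, and the test pointed up. S100a9 was at 1.42 ± 0.38 and its partner S100a8 at 0.56 ± 0.06, with rows at 0.01 and 1.12. The granule protein genes Ltf (-0.39 ± 0.05) and Ngp (-0.31 ± 0.17) were lower, Ngp having its row in a crowded stretch and losing its call without mouse 11 or 12 (highest adjusted p 0.156). Prtn3 (0.25 ± 0.08) lost its call when any 1 mouse was left out (highest adjusted p 0.268). Monocyte and macrophage markers were higher for 5 of 15 members, lower for 1 and not past the test for 9, also adjusted over the list alone (median 0.11, adjusted p = 0.15). The median was 0.24 without mouse 13 (adjusted p = 0.0808), and with the local median subtracted 2 members were higher, without Mpeg1, Aif1 and Fcer1g. The protease Ctss was at 0.48 ± 0.13 and the growth factor receptor Csf1r at -0.72 ± 0.33. Lyz2 (0.47 ± 0.31) and Mpeg1 (0.29 ± 0.09) lost their calls without mouse 11 or 13 (highest adjusted p 0.123 and 0.246), and Aif1 (0.31 ± 0.17), like Fcer1g, without mouse 11 or 12 (0.251).

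T and NK cell markers were higher for 2 of 7 members, lower for 0 and not past the test for 5, also adjusted over the list alone (median 0.03, adjusted p = 0.264). The granzyme Gzma was at 0.65 ± 0.27 and Cd4 at 0.34 ± 0.15, which lost its call without mouse 11 or 13 (highest adjusted p 0.101). Klrd1 (0.06 ± 0.26) and Cd247 (0.03 ± 0.18) did not pass. B and plasma cell markers were lower for 2 of 8 members, higher for 0 and not past the test for 6, also adjusted over the list alone (median -0.18, adjusted p = 0.199, and 0.0476 to 0.626 over the alternatives, the lowest without mouse 11). The immunoglobulin joining chain Jchain was at -0.67 ± 0.20 and the heavy chain Ighm at -0.50 ± 0.07, with rows from -1.32 to -0.06. Sdc1 (0.17 ± 0.05) and Cd22 (-0.18 ± 0.13) did not pass. Platelet and erythroid genes were higher for 1 of 7 members, lower for 2 and not past the test for 4, also adjusted over the list alone (median -0.05, adjusted p = 0.643). The platelet chemokine Pf4 was at 0.63 ± 0.19, the anion exchanger Slc4a1 at -0.76 ± 0.29 and Car1, in a crowded stretch, at -1.67 ± 0.54.

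Podocyte markers went both ways, with 2 of 11 members higher, 2 lower and 7 not passing, also adjusted over the list alone (adjusted p = 0.737). Their median was -0.003 and their mean 0.05, and the test pointed up. The filament gene Nes was at 0.74 ± 0.09 and the actin crosslinker Actn4 at 0.40 ± 0.10. The slit diaphragm gene Nphs1 (-0.36 ± 0.21) and the transcription factor Lmx1b (-0.34 ± 0.12) were lower. Without mouse 11 or 12 both lost their calls (highest adjusted p 0.191 and 0.134). Their means were then -0.27 and -0.34 for Nphs1, and -0.30 and -0.32 for Lmx1b. Genes of the basement membrane and matrix were higher for 5 of 21 members, lower for 0 and not past the test for 16, and higher for 6 adjusted over the list alone (median 0.09, adjusted p = 0.0696). The list passed without mouse 12 (adjusted p = 0.0221) and without crowded stretches (adjusted p = 0.0373), in a range of 0.0221 to 0.155 over the alternatives. Timp2, a metalloproteinase inhibitor, was at 0.52 ± 0.05 and Tgfbi at 0.64 ± 0.23. The collagens Col4a1 (0.39 ± 0.18), Col5a1 (0.34 ± 0.16) and Col3a1 (0.40 ± 0.31) lost their calls without mouse 11 or 13 (highest adjusted p 0.0944, 0.211 and 0.217). Endothelial and mesangial markers were higher for 2 of 16 members, lower for 1 and not past the test for 13, also adjusted over the list alone (median 0.01, adjusted p = 0.643). Beside Tagln, the smooth muscle actin Acta2 was at 0.46 ± 0.29, a call lost without mouse 12 (adjusted p = 0.0731). The endothelial receptor Eng was at -0.37 ± 0.15, a call lost without mouse 11 or 13 (highest adjusted p 0.0635).

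Among tubule markers no list passed. Proximal tubule markers were higher for 3 of 19 members, lower for 0 and not past the test for 16, and higher for 2 adjusted over the list alone (median 0.11, adjusted p = 0.253). The median was -0.01 with the local median subtracted and 0.03 without mouse 13. The glucose-6-phosphatase G6pc was at 0.45 ± 0.14. The anion transporters Slc22a6 (0.30 ± 0.03) and Slc22a8 (0.26 ± 0.09) lost their calls when any 1 mouse was left out (highest adjusted p 0.113 and 0.317). Their means stayed at 0.28 to 0.31 and at 0.21 to 0.30 in these refits. The phosphate transporter Slc34a1 was at -0.13 ± 0.15 (adjusted p = 0.307) and at -0.04 without mouse 12. Umod, a loop of Henle marker that the proximal list also held, was listed at 0 on all 3 arrays. Loop of Henle and distal tubule markers were lower for 5 of 9 members, higher for 0 and not past the test for 4 (median -0.31, adjusted p = 0.0696). Adjusted over the list alone, 5 were lower and 2 higher. The list passed without mouse 11 (adjusted p = 0.0128) and without crowded stretches (adjusted p = 0.0373), but its adjusted p reached 0.218 over the alternatives, and its median was -0.19 with the local median subtracted. The calcium-binding protein Pvalb was at -0.77 ± 0.24, the sodium-calcium exchanger Slc8a1 at -0.58 ± 0.15 and Calb1 at -0.48 ± 0.09. Slc8a1 and Calb1 each have a row in a crowded stretch, and with 1 row per gene Calb1 was at -0.18 (adjusted p = 0.131). The potassium channel Kcnj1 (-0.31 ± 0.07) and the growth factor Egf (-0.31 ± 0.07) lost their calls without mouse 11 or 12 (highest adjusted p 0.105 and 0.101).

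Collecting duct markers were lower for 5 of 15 members, higher for 0 and not past the test for 10, also adjusted over the list alone (median -0.03, adjusted p = 0.264, and 0.0386 to 0.865 over the alternatives, the lowest without mouse 11). The water channels Aqp4 and Aqp3 were at -0.86 ± 0.35 and -0.47 ± 0.20, the vasopressin receptor Avpr2 at -0.41 ± 0.15 and Slc4a1 at -0.76 ± 0.29, the last also counted among the erythroid genes. The intercalated cell factor Foxi1 (-0.44 ± 0.24) lost its call without mouse 11 or 13 (highest adjusted p 0.0814).

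Signalling and stress lists did not pass. JAK-STAT3 and SOCS targets were higher for 3 of 15 members, lower for 2 and not past the test for 10, with 3 higher and 3 lower adjusted over the list alone (median 0.01, adjusted p = 0.888). Stat3 itself was at 0.57 ± 0.14 and its feedback inhibitor Socs3 at -0.50 ± 0.29, beside Junb. Cebpb (0.37 ± 0.20) lost its call without mouse 12 or 13 (highest adjusted p 0.0862), and Socs1 (-0.37 ± 0.20) without mouse 12 (0.0903). p53 and apoptosis genes were higher for 3 of 16 members, lower for 1 and not past the test for 12, with 4 higher and 2 lower adjusted over the list alone (median 0.07, adjusted p = 0.478). The cell cycle inhibitor Cdkn1a was at 0.68 ± 0.18 and Gadd45a at 0.45 ± 0.14. The death receptor Fas (-0.36 ± 0.06) lost its call without mouse 11 (adjusted p = 0.0523), and Btg2 (0.30 ± 0.18), in a stretch, without mouse 12 or 13 (highest adjusted p 0.167). NRF2 targets were higher for 3 of 18 members, lower for 2 and not past the test for 13, with 6 higher and 2 lower adjusted over the list alone (median 0.10, adjusted p = 0.253). The metallothionein Mt2 was at 0.64 ± 0.17, the superoxide dismutase Sod2 at 0.46 ± 0.03 and the glutathione transferase Gstm3 at -0.50 ± 0.09. Slc7a11 (-0.27 ± 0.11) lost its call without mouse 11 or 12 (highest adjusted p 0.191), and Gclc (0.24 ± 0.04) when any 1 mouse was left out (0.284). Heat shock and ER stress genes were higher for 1 of 18 members, lower for 2 and not past the test for 15, with 2 higher and 5 lower adjusted over the list alone (adjusted p = 0.478). Their median was 0.002 and their mean -0.09, and the test pointed down. The disulfide isomerase Pdia6 was at -0.79 ± 0.21 and the chaperone Hspa1b at -0.76 ± 0.27, with rows at -1.17, in a crowded stretch, and -0.35. Asns (0.37 ± 0.13) lost its call without mouse 11 or 13 (highest adjusted p 0.0569).

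Metabolic lists did not pass either. Oxidative phosphorylation genes were higher for 4 of 10 members, lower for 0 and not past the test for 6, also adjusted over the list alone (adjusted p = 0.381). Their median was -0.05 and their mean 0.12, and the test pointed up. The complex I subunits Ndufa9 and Ndufs3 were at 0.55 ± 0.04 and 0.43 ± 0.04. Uqcrc1 (0.40 ± 0.15) lost its call without mouse 11 (adjusted p = 0.1), and Sdhc (0.30 ± 0.16) without mouse 11 or 13 (0.122). Fatty acid oxidation and peroxisome genes were higher for 4 of 20 members, lower for 0 and not past the test for 16, and higher for 6 adjusted over the list alone (median 0.16, adjusted p = 0.0935, and 0.0128 to 0.291 over the alternatives, the lowest without mouse 11). The peroxisome gene Pex11a was at 0.57 ± 0.13. Eci1 (0.40 ± 0.20), Pdk4 (0.45 ± 0.26) and Acadvl (0.34 ± 0.15) lost their calls without mouse 12 or 13 (highest adjusted p 0.0724, 0.0808 and 0.0859). Cholesterol and lipid synthesis genes were higher for 1 of 14 members, lower for 3 and not past the test for 10, with 3 higher and 3 lower adjusted over the list alone (adjusted p = 0.971). Their median was 0.05 and their mean -0.14, and the test pointed up. Beside Scd1, in a crowded stretch, its relative Scd2 was at -0.53 ± 0.18 and the lipid synthesis regulator Srebf1 at -0.41 ± 0.12. Fdft1 (0.26 ± 0.04) lost its call when any 1 mouse was left out (highest adjusted p 0.252). Hypoxia and glycolysis genes were higher for 2 of 15 members, lower for 0 and not past the test for 13, also adjusted over the list alone (median 0.01, adjusted p = 0.63). The vasodilator peptide gene Adm was at 1.02 ± 0.10 and Gapdh at 0.45 ± 0.10 over 8 rows, which ranged from 0.40 to 0.51.

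Lists kept as checks on the tissue and the time of day did not pass. Circadian clock genes were higher for 1 of 10 members, lower for 1 and not past the test for 8, also adjusted over the list alone (median 0.02, adjusted p = 0.895). Cry1 (0.30 ± 0.12) lost its call when any 1 mouse was left out (highest adjusted p 0.102), and Dbp (-0.43 ± 0.30) without mouse 11 or 12 (0.111). Glucocorticoid response genes were higher for 3 of 13 members (Cdkn1a, Mt2 and Pdk4), lower for 1 and not past the test for 9, with 4 higher and 3 lower adjusted over the list alone (adjusted p = 0.551). Their median was -0.01 and their mean 0.10, and the test pointed up. The lower member, Sult1a1 (-0.24 ± 0.04), lost its call when any 1 mouse was left out (highest adjusted p 0.25). By limma, 0 of 5 sex-linked or sex-biased genes passed, also adjusted over the list alone (median -0.05, adjusted p = 0.737). Among 10 genes of adrenal, liver, fat and muscle, which tissue beside the kidney could bring in, 0 passed, also adjusted over the list alone (median -0.10, adjusted p = 0.643). Albumin, Alb, was at -0.26 ± 0.11 (adjusted p = 0.0511, and over the alternatives from 0.0441 with quantile normalization to 0.227 with the plain test). Ribosomal protein genes were higher for 3 of 13 members, lower for 1 and not past the test for 9, also adjusted over the list alone (median 0.05, adjusted p = 0.478). Rplp0 was at 0.55 ± 0.12 and Rpsa at 0.49 ± 0.05. Rpl13 (-0.36 ± 0.15) lost its call without mouse 11 or 13 (highest adjusted p 0.0706), and Rpl19 (0.30 ± 0.13) when any 1 mouse was left out (0.135). Housekeeping genes were higher for 2 of 7 members, lower for 0 and not past the test for 5, and higher for 4 adjusted over the list alone (median 0.22, adjusted p = 0.0738, and 0.0434 to 0.173 over the alternatives). The list passed without mouse 12 (adjusted p = 0.0462) and with rows measured on at least 2 arrays (0.0434), and its median was 0.09 with the local median subtracted. The tubulin gene Tubb5 was at 0.65 ± 0.10, beside Gapdh. The actin gene Actb had a row listed at 0 on all 3 arrays and a row at -0.06, 0.23 and 0 in mice 11, 12 and 13.

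The last question was how far the mice agreed. Across the 7235 genes, log ratios of mice 11 and 12 had a Pearson correlation of 0.752 (Spearman 0.669), mice 11 and 13 of 0.687 (0.612) and mice 12 and 13 of 0.594 (0.49). Genes are not independent replicates, and a shared pool and dye orientation make the arrays correlate without any effect of the antibody. The sign was the same in all 3 mice for 4086 genes (56.5%), against 25% by independent signs. Of 1103 genes with several rows, 477 had rows of opposite sign, and among the 148 of them past the test 12 did. Rows of opposite sign average towards 0 before the test, so a lower share among called genes is partly built in.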

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

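Keeping exact zeros, subtracting the local median and leaving out crowded stretches were chosen after seeing the data. The 3 centring and scaling settings, robust moderation, rows measured on at least 2 arrays, 1 row per gene, the local median and leaving out crowded stretches gave between 1216 and 1529 genes past the threshold, against 1407, and 1585 to 2048 rows where rows were counted, against 1902. Of the 1407 genes, 1402 were shared with robust moderation, 1132 with the local median and 1109 with rows on at least 2 arrays, all with the same sign. With 1 row per gene 1318 were shared, 1317 with the same sign, and without crowded stretches 1269 of the 1303 still tested, 1267 with the same sign. Leaving out 1 replicate gave 726 to 1032 genes and 944 to 1445 rows, with the lowest counts without replicate 1, and 676, 860 and 879 genes were shared without replicates 1, 2 and 3. A plain test without moderation, which has only the 3 arrays of each gene to estimate its spread, called 3 genes and 3 rows (1634 and 2135 at an unadjusted p under 0.05). With exact zeros kept as values, 31 of 10698 genes and 31 of 16281 rows passed (2228 and 2873 unadjusted), and the cause was not tested. In that setting the mean correlation between mice was 0.597 against 0.677. A limit of 2-fold left 56 genes and 82 rows if the base is 2, by its own construction, and 1130 genes and 1594 rows if it is 10.

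Of the 34 lists, 4 passed, and 5 to 8 passed with 1 replicate left out. With an estimated correlation 0 lists passed by camera, and 1 list had an unadjusted p under 0.05. Their medians are unaffected by this setting, at 0.651 (cell cycle), 0.433 (immediate early), 0.413 (acute-phase and injury) and 0.251 (antigen presentation) for the 4 lists. For cell cycle a larger correlation is argued against as the cause, because its estimate was -0.0317, below the preset 0.01. The estimates were above the preset for immediate early (0.216), acute-phase and injury (0.243) and antigen presentation genes (0.651). Each estimate rests on 3 arrays. The 2 settings also differ in their degrees of freedom, which come from the arrays with an estimated correlation and from the number of genes with the preset one. The loss of all lists is therefore little evidence against them. How much the larger estimates added for the lists other than cell cycle was not tested. With the sign turned the medians were -0.651, -0.433, -0.413 and -0.251. These 4 lists passed in the same direction under each other alternative run for lists. Their medians moved by less than 1.5 times, while 28 of the 30 other medians moved by more under an alternative, 14 of them through 0. With the local median subtracted, members higher went from 5 to 2 (monocyte), 5 to 3 (matrix), 2 to 1 (T and NK) and 3 to 5 (NRF2), and members lower from 5 to 3 (loop) and 2 to 4 (heat shock). Ranges of adjusted p for lists over alternatives exclude the estimated correlation. Of 149 genes named by rule 123 passed, of which 37 moved by over 1.5 times under an alternative, 14 of them under one other than keeping zeros. The calls lost were 29, 19 and 23 without replicates 1, 2 and 3, 9 with the local median (Mpeg1, Cd4, Lmx1b, Col5a1, Kcnj1, Btg2, Asns, Acadvl and Fdft1), 11 with rows on at least 2 arrays, 7 with 1 row per gene and 2 without centring, and all 123 with the plain test or with zeros kept. Without crowded stretches 1 call was lost and 20 named genes were not tested. Traf2, among the 7, was at 0.0171 with 1 row per gene, since its rows disagree. No paired analysis was possible because there is only 1 group and all arrays share 1 pool. A filter on dim rows was not run, as signals and background were not used here, so what they limit is unknown.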

Other observations

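The scan of gene families, the count of neighbours among the lowest rows and the tests of a shared shift for them, of white blood cell markers and of levels too low to measure were chosen only after the result was seen.

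In a scan of 96 groups of genes whose symbols share a stem, 3 passed camera with the preset correlation. With an estimated correlation, which leaves camera little power on 3 arrays, the adjusted p was 0.989 for each of them. The Psmb group, proteasome beta subunits and the pseudogene Psmb5-ps, was higher for 5 of 9 members including Psmb5-ps (0.29 ± 0.10), with a median of 0.30 (adjusted p = 0.0208). Psmb8 was at 0.60 ± 0.21, Psmb4 at 0.43 ± 0.09, Psmb3 at 0.42 ± 0.08 and Psmb6 at 0.33 ± 0.13, and Psmb8 is also in 2 of the lists above. The Mcm group, mostly replication helicase subunits, was higher for 5 of 8 (median 0.71, adjusted p = 0.00456), and these 5 are also cell cycle list members. Vomeronasal receptor genes, which act in the sense of smell, were lower for 5 of 13 (median -0.20, adjusted p = 0.0208). Vmn2r10 was at -0.42 ± 0.12 and Vmn1r43 at -0.34 ± 0.02, but with the local median subtracted the adjusted p of the group was 0.0766. Signals were not used, so whether the rows of these receptors measured any kidney transcript was not tested.

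The lowest values sat at neighbouring row numbers. Of 68 rows below -1, among those measured on 2 or 3 arrays, 70.6% had at least 3 others within 100 row numbers, against at most 22.1% in 1000 random reassignments, and 19 pairs were directly adjacent against at most 3. Lower transcript levels of the genes named are argued against: 17 other rows of 16 of these genes had a median of 0.0799 (bootstrap 95% interval -0.154 to 0.269), where the crowded rows were at -1.92. A shift shared by most rows of a local window (15 places by 7 lines), as the whole cause, is argued against too. The 48 crowded rows went from a median of -1.87 to -1.83 with the local median subtracted, and 48 stayed below -1. A shift of fewer rows in a window would barely move its median, so such a shift was not tested. The cause stays open, since the neighbour counts only describe the pattern, and so do genes with no other row.

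The cell cycle list passed under each alternative run for lists except an estimated correlation, and turned with the sign. A shift shared by most rows of a local window is argued against. The list's median was 0.634 with the local median subtracted, and 17 of 17 calls were kept. Dividing white blood cells that entered the kidney cannot be told apart from dividing kidney cells: 42 white blood cell markers had a median of 0.0404 (95% interval -0.0134 to 0.104), with 10 higher and 5 lower, and S100a9, the highest, at 1.42. A difference between the normal pool and these mice other than the antibody, such as age, or a dye bias of the probes may also contribute. Neither was tested, as no dyes were swapped and no control mouse had an array of its own.

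Exact zeros fell on abundant genes, and also on receptor genes of smell and taste. Rows of ribosomal protein and oxidative phosphorylation genes were at 0 on all 3 arrays for 34 of 63, or 54% (exact 95% interval 40.9% to 66.6%), against 21.1% of 13675 other named rows (Fisher's exact test, p = 1.22e-08), which argues against low levels as the whole cause. Signals too bright to use, as the whole cause, are argued against by these receptor genes. Of their 135 rows 31.1% were at 0 on all 3 arrays (23.4% to 39.6%), also above 21.1%. Both causes together, or a spot filter of the authors, may apply and were not tested, and no biological explanation was tested.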
